A study of Mus musculus with 6 samples.

How the data were processed

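The data are 3' end RNA-seq profiles of mouse CD8 T cells, the cytotoxic branch of the T cell lineage. Per the labels' protocols, naive CD8 T cells from the spleen of female C57BL/6 mice were stimulated for 2 days through the T cell receptor with antibodies to TCR-beta (3 µg/ml) and CD28 (1 µg/ml) in the presence of interleukin-2 (10 ng/ml). They were then kept in interleukin-2 until day 7. The mice were labelled wild type or Menin knockout. Menin, the product of Men1, is a scaffold protein of histone H3K4 methyltransferase complexes. There were 3 libraries per genotype, made from 500 ng of total RNA with the QuantSeq 3' mRNA kit, which reads near the polyadenylated end of each transcript and gives 1 read per captured fragment. The series' design text mentions several days of culture, and only day 7 was analysed here.

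Each of the 6 deposited files holds 1 value per gene for 1 library, as counts scaled to a total of 1000000 per library (CPM), and each column covers 41708 genes. A further row of each file had an empty cell and was left out. The build GRCm38 (mm10) is named in the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. No scaling between libraries beyond the total was visible in the values the authors deposited. All values of every column (100%) were whole multiples of 1 read within a tolerance of 0.01 reads, so the reads behind each CPM value were recovered. They came to 1042178, 1068806 and 1048131 reads for wild type replicates 1 to 3, and to 1187185, 1496933 and 1090228 for the knockout replicates. These totals cover reads counted in genes. A gene seen with 3 reads stood at 2.00 to 2.88 CPM, which was taken as the detection floor per library. The kit's reads were treated as counted without molecular identifiers, so floors and intervals cover counting error only.

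Gene identifiers were matched to symbols for 38618 genes, and 3090 were not matched and held at most 0.0351% of the reads of a library. Coordinates are 1-based positions of the GENCODE annotation of GRCm38. Of the listed genes 28290 stood at 0 in every library. Values above 0 were almost confined to protein-coding genes, with 13369 of 21829 above 0 against 6 of 5597 long intergenic non-coding RNAs and 0 of 494 T cell receptor and immunoglobulin gene segments. Genes of those classes are listed at 0 in the files, and a 0 there was read as uninformative.

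The test was planned as edgeR's quasi-likelihood test on counts. The recovered reads allowed that test too, and it was run as an alternative. Because the files hold CPM, the main test was changed to limma (version 3.58.1 in R 4.3.3) on log2(CPM + 1). The CPM were first scaled by TMM factors from edgeR 4.0.16. The limma fit used a moderated test with an intensity trend and robust variance estimation, and all 6 libraries entered with genotype as the only term. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15) on the recovered reads, which left 7878. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are knockout over wild type on the log2(CPM + 1) scale and understate the change of genes with low values. Means and SD are of TMM-scaled CPM with n = 3 per genotype. Unless another test is named, every adjusted p of a single gene is limma's. For genes with 1 to 3 reads in 1 genotype, the ratio of reads per total is given with an exact 95% binomial interval of the pooled reads. For genes with 0 reads in 1 genotype, the fold was computed against 3 reads per library and stands as a lower bound.

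Before the data were examined, 42 gene lists were fixed, of which 30 were pathways of activated T cells, 3 were signs of RNA quality and 9 were markers of cell types, including CD8 T cells themselves. The pathway lists covered cytotoxic effectors, naive and memory genes, inhibitory receptors, cyclin-dependent kinase inhibitors, the secretory phenotype of senescent cells, type 2 and interleukin-17 programs, S phase and G2/M phase. They also covered glycolysis, hypoxia, glutamine use, the tricarboxylic acid cycle, the respiratory chain, ATF4 and serine synthesis, cholesterol, fatty acids, the unfolded protein response, p53 targets, the BCL2 family, Menin partners and KMT2 complexes, Polycomb, Hox genes, AP-1 factors, interferon response, homing, cytokine receptors, T cell receptor signalling, natural killer (NK) receptors and autophagy. Lists with at least 3 tested genes, 36 in number, were tested two-sided with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists. Library measures were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

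The genes named in the text were set by a rule: Men1, Kmt2a, Cd3e, Cd8a, Cd8b1 and Cd4. To these it added the 12 largest changes in each direction among called genes with a mean of at least 5 CPM, a symbol that is not a predicted model and no overlap between the genotypes. From each list it took up to 4 called members per direction, or up to 2 of the most abundant members where none was called. Thy1, Lck, Cd44, Slc3a2, Gbp4 and Hsp90ab1, which complete counts of 5 or fewer, were chosen after their values were seen. Some genes that the rule names are not reported here. The choices tried as alternatives were the scaling (DESeq2 1.42.0 size factors, library totals alone), the filter, DESeq2's Wald test and limma voom on the recovered reads, non-robust estimation, a replicate block, the removal of the 10 most abundant genes and the omission of each library. For lists they were an estimated correlation, fry and ranks. Chosen after seeing the data were pseudocounts of 0.5 and 4, reads thinned to the smallest library and a correction of fold changes for transcript length and GC content. The planned edgeR quasi-likelihood test, run on the recovered reads, was also added as an alternative only then. The quasi-likelihood test called 2660 genes, of which 2567 were also called by limma.

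The procedure was tested on simulated counts with the wild type means, in which 50 genes each were changed by set folds among 7755 tested genes. It called 33 of 50 genes raised 1.5-fold, 46 of 50 raised 2-fold, 50 of 50 raised 4-fold and 36 of 48 tested genes lowered 0.5-fold, with 6 of 171 calls (3.51%) false. Changes were seeded only in genes above a minimum wild type level, and every gene had the same dispersion (0.00866). Far fewer genes changed than in the data. The rates therefore do not cover low genes, genes of larger spread or the false share of the real calls. Replicates of 1 genotype differed beyond sampling noise in every pair (chi-square per degree of freedom 1.51 to 1.84), against 9.75 to 10.8 between genotypes, so no library was taken for a duplicate of another. The labels call the libraries biological replicates but do not say whether any shared an animal or litter. The p-values therefore measure the spread between these samples. Figures were drawn with matplotlib 3.10.9.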

Results

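Gene expression was profiled in 3 wild type and 3 Menin knockout cultures of splenic CD8 T cells on day 7 after stimulation through the T cell receptor. Each library held 1042178 to 1496933 reads assigned to genes, and the wild type libraries held fewer reads than the knockout libraries. Between 11074 and 11149 genes had at least 1 read in the wild type libraries and 11302 to 11654 in the knockout libraries. The comparison asks which transcripts of activated CD8 T cells differ between Menin knockout and wild type. Values are TMM-scaled CPM, mean ± SD, n = 3 per genotype.

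The targeted gene Men1 (ENSMUSG00000024947; GRCm38 chromosome 19, 6334979 to 6340891, plus strand) had 32, 28 and 37 reads in wild type replicates 1 to 3 and 12, 11 and 13 in knockout replicates 1 to 3. Its level fell from 29.5 ± 4.44 to 10.2 ± 2.44 CPM, a log2 fold change of -1.46 (SE 0.28, adjusted p = 6.03e-05), and every knockout library lay below every wild type library. The deleted part of the gene is not given in the labels, and 3' end reads outside it would not report the deletion. The remaining reads therefore do not show how complete the deletion was. Kmt2a, which encodes a methyltransferase that binds Menin, stood at 278 ± 24.1 CPM in wild type and 319 ± 41.5 CPM in knockout cells (adjusted p = 0.113). It passed the threshold only after the length and GC correction, at a log2 fold change of 0.26. In the list of Menin's partners and of subunits of KMT2 methyltransferase complexes with or without Menin, 0 of 18 genes rose and 3 fell, namely Psip1 (log2 fold change -0.57), Pagr1a (-0.42) and Kmt2c (-0.35), and 1 of them passed when adjusted over the list alone (list median -0.11, camera adjusted p = 0.284). Kmt2c and Pagr1a belong to complexes without Menin. The median was -0.18 without wild type replicate 3 and -0.23 under library totals. With DESeq2, with no filter beyond 1 read, or without wild type replicate 3 or knockout replicate 2, 1 of them was called, and 5 fell with library totals alone. Pagr1a was not called with no filter or DESeq2 or without wild type 2 or 3 or knockout 1 or 2, -0.43 to -0.38. Kmt2c was not called with no filter, DESeq2, thinned reads or the length and GC correction or without wild type 1 or 3 or knockout 2 or 3, -0.38 to -0.24.

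T cell identity genes shifted in both directions. The CD3 chain genes Cd3e (from 265 ± 8.59 to 340.0 ± 29.8 CPM, adjusted p = 0.00172), Cd3d (log2 fold change 0.30) and Cd3g (0.46) rose together with Thy1 (0.29) and Runx3 (0.38), a transcription factor of the CD8 lineage. The co-receptor genes Cd8a (from 241 ± 38.1 to 141 ± 9.48 CPM, adjusted p = 7.40e-07) and Cd8b1 (from 397 ± 8.60 to 182 ± 5.45 CPM, adjusted p = 2.04e-13) fell, as did Cd2 (-0.72), the zeta chain gene Cd247 (-0.47) and the kinase gene Lck (-0.23). In total 5 of 10 tested identity genes rose and 5 fell, also when adjusted over the list alone (median 0.03, mean -0.15, camera adjusted p = 0.679). Cd4 is listed at 0 in all 6 libraries.

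Menin knockout cells carried far more transcript of a block of granzyme genes and less of genes that mark naive and memory T cells, a list whose fall was not called with an estimated correlation (adjusted p = 0.131). They also held less mRNA of the mitotic machinery and more of the chaperones of the endoplasmic reticulum. Of 7878 tested genes, 2592 (32.9%) changed, 1330 of them higher and 1262 lower in the knockout, and 763 changed at least 2-fold (354 higher, 409 lower). The 3 values of each genotype did not overlap for 3397 genes (43.1%), where chance gives 10%, and 2453 of the called genes were among them. With library totals in place of TMM factors the median of all genes shifted by -0.12 on the log2 scale. The calls then split into 917 higher and 1745 lower (34.4% higher against 51.3% with TMM), so small changes are read relative to the TMM scale. DESeq2's Wald test called 1703 genes (869 higher, 834 lower), of which 1702 were also called by limma.

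Granzymes led the genes that rose. Gzmd (ENSMUSG00000059256; chromosome 14, 56129556 to 56132608), a serine protease of cytotoxic granules, rose from 10.1 ± 8.92 to 2362 ± 33.1 CPM (log2 fold change 8.04, SE 0.64, adjusted p = 0.00107). Gzme rose from 1.22 ± 1.41 to 457 ± 27.5 CPM, Gzmg from 4.88 ± 4.74 to 663 ± 18.3 CPM, Gzmc from 1.53 ± 1.40 to 255 ± 18.97 CPM and Gzmf from 1.21 ± 1.05 to 78.3 ± 15.2 CPM. These genes lie side by side on chromosome 14 and are close copies of each other, so the share of reads assigned to each is uncertain. The neighbouring protease gene Mcpt8 had 482 knockout and 3 wild type reads, a ratio of 134 (45.7 to 654) with its 95% interval. Fcer1g (ENSMUSG00000058715; chromosome 1, 171229572 to 171234365), the signalling chain shared by Fc receptors and NK receptors, had 615 knockout and 2 wild type reads, a ratio of 257 (70.9 to 2130.0). The actin-severing gene Scin showed a ratio of 93.2 (31.6 to 454) and the matrix gene Npnt one of 59.01 (16.04 to 492). Cntn1, a neuronal adhesion gene, rose from 1.21 ± 1.05 to 81.6 ± 2.35 CPM.

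Tmem119 and Sema6d were at 0 reads in every wild type library. Against 3 reads per library, Tmem119 was at least 19.9-fold higher in the knockout (59.1 ± 0.278 CPM) and the semaphorin gene Sema6d at least 10.8-fold higher (31.96 ± 7.87 CPM). Among the genes that fell, Dapl1 had 129 wild type reads and 1 knockout read, a wild type to knockout ratio of 154 with an interval of 27.2 to 6134. The chromatin organiser Satb1 (ENSMUSG00000023927; chromosome 17, 51736187 to 51833290) fell from 364 ± 22.6 to 28.2 ± 2.30 CPM (log2 fold change -3.64, SE 0.13, adjusted p = 5.35e-25). Il6st, the shared receptor chain of the interleukin-6 family, fell from 19.4 ± 1.83 to 1.34 ± 1.32 CPM, the lymphoid transcription factor gene Ikzf3 from 26.4 ± 4.95 to 2.69 ± 3.07 CPM, and Tox from 14.9 ± 4.74 to 1.08 ± 0.272 CPM. The transglutaminase gene Tgm2 fell from 91.5 ± 24.5 to 10.8 ± 4.69 CPM and the DNA demethylase gene Tet1 from 26.4 ± 6.83 to 2.74 ± 0.804 CPM. The adhesion receptor gene Crtam and the membrane protein gene Ms4a4c fell by log2 fold changes of -2.68 and -2.67.

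**Figure D1:**
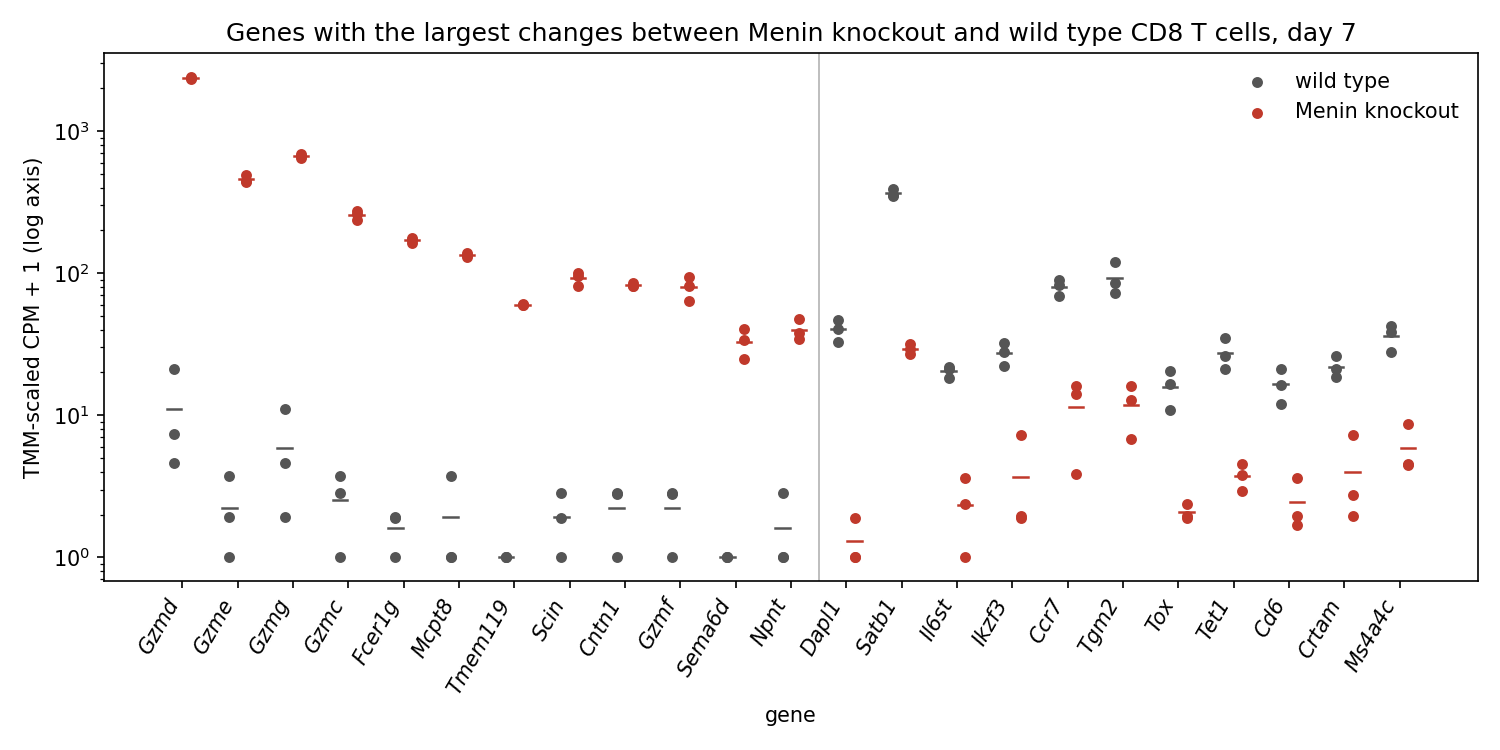
TMM-scaled CPM + 1 on a log axis for the 12 genes with the largest rise (left of the line) and 11 of the 12 with the largest fall in Menin knockout CD8 T cells at day 7. Points are single libraries (3 per genotype) and short bars are means; for each gene the 3 knockout values lie on 1 side of the 3 wild type values.

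Cytotoxic effector genes rose as a group. Of 23 tested members 16 rose and 3 fell, with the same counts when adjusted over the list alone (median log2 fold change 0.85, camera adjusted p = 4.46e-10, adjusted p = 0.0354 with an estimated correlation). With a trend of fold change on transcript length and GC content removed, the median was 0.73, and its bootstrap interval over genes (-0.08 to 1.80) spanned 0. The list's mean, 1.96, includes log2 fold changes of 6.86 to 8.04 for Gzmc, Gzmg, Gzme and Gzmd, whose read shares are uncertain. Gzmc and Gzme had 5 and 4 wild type reads and passed the filter only through their knockout reads. Without the filter the list's median lay nearer 0. The members that fell were Klrk1, the gene of the activating receptor NKG2D (from 69.3 ± 10.2 to 26.7 ± 3.49 CPM), Klrd1 (from 61.98 ± 7.25 to 33.5 ± 5.66 CPM) and Tbx21, the gene of the transcription factor T-bet (log2 fold change -0.84, adjusted p = 0.0274). Tbx21 was not called with DESeq2 or without wild type replicates 1 or 2 or knockout replicates 2 or 3 (log2 fold change -0.84 to -0.62). Genes for NK receptors that activated T cells can acquire went both ways, with 3 of 6 higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.250). Klrb1c, the gene of NK1.1, rose from 5.46 ± 3.29 to 87.7 ± 11.3 CPM and Cd244a, the gene of the receptor 2B4, from 15.5 ± 2.36 to 97.8 ± 5.58 CPM, beside Fcer1g. Klrc1 fell with Klrk1 and Klrd1 (log2 fold change -0.72), a call lost without wild type replicates 2 or 3, without knockout replicate 2 and after the length and GC correction (-0.64 to -0.52). Beside these groups, 4 of 5 tested markers of myeloid cells were also higher in the knockout, while most of the 22 listed were too low to test.

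Naive and memory genes fell. Of 23 tested members 13 fell and 3 rose, or 13 and 4 when adjusted over the list alone (median -0.77, camera adjusted p = 2.73e-06). The list's adjusted p = 0.131 with an estimated correlation. Ccr7 (ENSMUSG00000037944; chromosome 11, 99144196 to 99155077), which encodes a chemokine receptor of lymph node homing, fell from 79.5 ± 10.4 to 10.3 ± 6.53 CPM (adjusted p = 0.0154), next to Dapl1 and Satb1. The members that rose were Actn1 (log2 fold change 0.70, not called with DESeq2 or without wild type 3 or knockout 1, 0.44 to 0.68), Txk (0.46) and Eomes (0.25). Txk was not called with library totals, DESeq2 or thinned reads or without wild type 1 or 3 or knockout 2 or 3, 0.34 to 0.48. Eomes was not called with library totals, no filter, a 5 CPM filter, DESeq2 or the length and GC correction or without wild type 1 or 3 or knockout 2 or 3, 0.13 to 0.25. Of these, 0 were called with DESeq2 or without wild type replicate 3. With library totals alone, or without wild type replicate 1, knockout replicate 2 or knockout replicate 3, 1 was called. Beside the fall of these genes, some markers known from myeloid cells rose, though most were too low to test.

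Genes of inhibitory receptors and of exhaustion rose on balance, with 8 of 12 higher and 1 lower, also when adjusted over the list alone (median 0.67, camera adjusted p = 8.76e-04, adjusted p = 0.292 with an estimated correlation). This median also lay nearer 0 without the filter. Havcr2, the gene of TIM-3, rose from 26.6 ± 10.3 to 144 ± 30.8 CPM, Pdcd1, the gene of PD-1, from 3.36 ± 3.50 to 19.2 ± 4.71 CPM, and the nuclear receptor gene Nr4a3 from 4.56 ± 1.85 to 25.7 ± 3.71 CPM. The member that fell was Tox, a transcription factor gene of exhausted T cells. Genes of T cell receptor signalling and co-stimulation fell on balance, with 17 of 29 lower and 3 higher, also when adjusted over the list alone (median -0.34, camera adjusted p = 6.72e-04, adjusted p = 0.221 with an estimated correlation). Cd6 (from 15.5 ± 4.51 to 1.43 ± 1.06 CPM), the co-stimulatory receptor gene Cd226 (from 86.5 ± 2.40 to 16.4 ± 1.66 CPM), Cd5 (from 31.9 ± 4.33 to 8.54 ± 2.96 CPM) and the phosphatase gene Ptpn6 (log2 fold change -1.25) fell. Tnfrsf9, the gene of 4-1BB (from 953 ± 4.23 to 2185 ± 116 CPM), Icos (from 119 ± 23.7 to 246 ± 18.7 CPM) and the ubiquitin ligase gene Cblb (0.78) rose.

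Receptors for cytokines and homing changed in both directions. The interleukin-2 receptor beta chain gene Il2rb rose from 572 ± 13.6 to 1166 ± 55.4 CPM, with Tgfbr2 (log2 fold change 0.89) and Il12rb1 (0.49). In turn 9 of 19 cytokine receptor genes fell, or 10 when adjusted over the list alone. Il12rb2 (-1.19), Il18rap (-0.98) and Ifnar2 (-0.94) were among them (camera adjusted p = 0.0913). The list was called without the filter (0.0252), with a 5 CPM filter (0.0363) and without knockout replicate 1 (0.0234). Il12rb1 was not called with library totals, DESeq2 or the length and GC correction or without wild type 1 or knockout 1 or 2, 0.37 to 0.51. Of 17 chemokine receptor and trafficking genes 9 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.140). The collagen-binding integrin gene Itga1 rose from 5.18 ± 3.51 to 137 ± 3.05 CPM, the chemokine receptor gene Cxcr6 from 46.2 ± 12.9 to 131 ± 6.55 CPM and Ccr2 from 485 ± 28.4 to 839.8 ± 38.6 CPM, with Itgb1 at 0.98. Cxcr4 (log2 fold change -1.01) and S1pr1 (-0.78) fell next to Ccr7 and Cd44 (-0.48). S1pr1 was not called with a pseudocount of 0.5 or the length and GC correction or without wild type 1 or 3 or knockout 2 or 3, -0.79 to -0.53.

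The mitotic program was lower in the knockout in every tested gene of its list. All 32 G2/M genes fell, also when adjusted over the list alone (median -1.20, camera adjusted p = 7.06e-26, adjusted p = 0.00859 with an estimated correlation). Top2a (ENSMUSG00000020914; chromosome 11, 98992943 to 99024189), the topoisomerase of mitotic chromosomes, fell from 2976 ± 102 to 1011 ± 64.1 CPM (SE 0.05 of a log2 fold change of -1.56, adjusted p = 1.78e-25). The mitotic kinase gene Aurkb fell from 32.7 ± 9.23 to 10.8 ± 1.84 CPM, with Ckap2 (log2 fold change -1.48) and Anln (-1.45). Of 29 S phase genes 20 fell and 0 rose, or 23 and 0 when adjusted over the list alone (median -0.64, camera adjusted p = 7.08e-08, adjusted p = 0.221 with an estimated correlation). Dtl fell from 35.8 ± 6.13 to 13.1 ± 4.63 CPM, Clspn from 103 ± 15.3 to 47.4 ± 2.15 CPM, Uhrf1 from 159 ± 9.20 to 75.9 ± 7.93 CPM, and Cdc45 by a log2 fold change of -1.33, a call lost without wild type replicate 3 (-1.05).

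Inhibitors of cyclin-dependent kinases split into 3 that rose and 3 that fell among 6 tested, also when adjusted over the list alone (camera adjusted p = 0.679). Cdkn1a, the gene of p21, rose from 514 ± 21.8 to 1022 ± 44.7 CPM, Cdkn2a from 138 ± 12.1 to 273 ± 16.7 CPM and Cdkn2b from 12.1 ± 4.998 to 47.3 ± 4.75 CPM. Cdkn2c fell from 38.2 ± 6.54 to 11.6 ± 2.69 CPM, Cdkn1b from 146 ± 17.6 to 71.7 ± 6.98 CPM and Cdkn2d from 139 ± 5.15 to 83.1 ± 13.1 CPM. Of the secreted factors of senescent cells 5 were tested, and Spp1, the gene of osteopontin, rose from 53.8 ± 7.25 to 635 ± 36.5 CPM (adjusted p = 5.63e-27) while Igfbp4 fell (log2 fold change -0.87). When adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.272), and 2 were also called higher with voom, edgeR, or without wild type replicate 3 or knockout replicate 1. Of 3 tested genes of type 2 and regulatory cytokine programs, Maf rose (0.79) and Gata3 fell (-0.77), also when adjusted over the list alone (camera adjusted p = 0.745). The interleukin-17 list had 1 tested gene, Rora, which fell (log2 fold change -0.72).

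Chaperones and folding enzymes of the endoplasmic reticulum rose together. Of 21 tested genes of the unfolded protein response 17 rose and 0 fell, or 18 and 0 when adjusted over the list alone (median 0.93, camera adjusted p = 1.07e-11, adjusted p = 0.0257 with an estimated correlation). Calr (ENSMUSG00000003814; chromosome 8, 84841850 to 84846934), which encodes calreticulin, rose from 338 ± 16.6 to 1186 ± 30.4 CPM (log2 fold change 1.81, SE 0.07, adjusted p = 6.34e-24). Hspa5, the gene of the chaperone BiP, rose from 464 ± 10.3 to 1213 ± 64.97 CPM, Pdia6 from 85.2 ± 14.1 to 258 ± 9.04 CPM and Hyou1 from 27.9 ± 2.32 to 77.6 ± 2.41 CPM. Targets of the transcription factor ATF4 and genes of serine synthesis rose on balance, with 7 of 27 higher and 0 lower, or 6 and 0 when adjusted over the list alone (median 0.22, camera adjusted p = 0.0329, adjusted p = 0.352 with an estimated correlation). Atf5 rose from 12.4 ± 2.003 to 34.1 ± 6.22 CPM, Ppp1r15a from 8.21 ± 2.47 to 22.2 ± 4.85 CPM and Pycr1 from 14.9 ± 3.59 to 37.1 ± 6.13 CPM. Slc7a3 rose by 2.02 but not with DESeq2, nor without wild type replicates 2 or 3 or knockout replicates 2 or 3 (1.61 to 1.98). The median was 0.13 without wild type replicate 3 and 0.10 under library totals. The list's shift was not called without wild type replicate 3 (adjusted p = 0.0658), without knockout replicate 3 (0.0653) or after the length and GC correction (0.0969), and 4 members rose with DESeq2 or without knockout replicate 3.

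Genes of energy metabolism moved little. Of 48 nuclear genes of the respiratory chain and ATP synthase 14 rose and 0 fell, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.00876, adjusted p = 0.352 with an estimated correlation). Atp5g1 rose from 105 ± 12.7 to 189 ± 4.92 CPM, Uqcrq from 119 ± 12.4 to 201 ± 6.08 CPM and Cox7b by 0.51 on the log2 scale. DESeq2 called 9 higher. With library totals alone 7 rose and 2 fell (median 0.03, camera adjusted p = 0.0805), and after the length and GC correction 7 rose and 1 fell (median 0.02, camera adjusted p = 0.569). Of 20 glycolysis genes 7 fell and 0 rose, also when adjusted over the list alone (median -0.13, camera adjusted p = 0.124). Among them were Pfkfb3 (from 50.4 ± 10.5 to 22.4 ± 5.03 CPM), Pfkp (from 574 ± 4.76 to 408 ± 18.4 CPM), Pfkm (not called with DESeq2 or without wild type 1 or 2, -1.11 to -0.84), and Pdk1 (log2 fold change -0.49). The list was called with library totals alone, where 13 fell (median -0.25, camera adjusted p = 0.0169), without the filter (0.0262) and after the length and GC correction (0.0210). The Pdk1 call was lost with DESeq2 and without knockout replicate 3.

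Other metabolic lists were not called. Of 14 genes of glutamine use 5 rose and 0 fell, or 6 and 0 when adjusted over the list alone. They included the transporter gene Slc1a5 (from 47.01 ± 7.23 to 81.9 ± 19.8 CPM) and Gfpt1 (log2 fold change 0.64; camera adjusted p = 0.265). Cad (0.71) and Asns (0.51) rose with Slc3a2 (0.46), but Cad was not called with DESeq2 or without wild type 1 or knockout 2 or 3, 0.47 to 0.70. Asns was not called with library totals or DESeq2 or without wild type 3 or knockout 3, 0.39 to 0.52. With DESeq2 or without knockout replicate 3, 3 members rose, and 3 fell with library totals alone. Of 26 genes of the tricarboxylic acid cycle Mdh2 rose (0.31) and Idh2 fell (-1.06), also when adjusted over the list alone (camera adjusted p = 0.432). Mdh2 was not called with library totals alone, without wild type replicate 1 or after the length and GC correction (0.19 to 0.25), and Idh2 was not called with DESeq2. With library totals alone 0 members of this list rose and 4 fell, and 2 fell without wild type replicate 2 or after the length and GC correction. Of 16 hypoxia genes Ero1l rose (0.60) and 6 fell, including Egln1 (-0.75), P4ha1 (-0.55), P4ha2 (-0.83) and Hif1a (-0.37), or 2 and 7 when adjusted over the list alone (camera adjusted p = 0.432). Without wild type replicate 2 or knockout replicate 2, 3 hypoxia genes fell, and 3 rose with voom or without wild type replicate 3. There were 2 that rose without the filter, with non-robust estimation or edgeR, or without wild type replicate 2 or knockout replicates 1 or 3. P4ha2 was not called with DESeq2, non-robust estimation or thinned reads or without wild type 1 or 2 or knockout 1, 2 or 3, -0.98 to -0.63. Hif1a was not called with the length and GC correction or without wild type 2 or knockout 2, -0.29 to -0.19. Of 22 cholesterol genes Ebp (0.39), Msmo1 (0.35) and Hmgcs1 (0.23) rose and 1 fell, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.535), but 0 rose and 5 fell with library totals alone. With DESeq2 or without knockout replicate 3, 1 of them rose, and 6 rose after the length and GC correction. Ebp was not called with library totals or DESeq2 or without wild type 1 or 2 or knockout 2 or 3, 0.27 to 0.40. Msmo1 was not called with library totals or DESeq2 or without wild type 3 or knockout 3, 0.23 to 0.35. Of 21 fatty acid genes 2 rose, Etfb (from 98.6 ± 16.8 to 197 ± 15.6 CPM) and Cpt1a (0.56). The 4 that fell were Elovl5 (from 160.0 ± 9.57 to 78.3 ± 3.82 CPM), Fads1 (-0.96), Acadm (-0.59) and Scd1 (-0.33), also when adjusted over the list alone. The list was not called (median 0.01, mean -0.08, camera adjusted p = 0.570). Under library totals 9 of them fell, and with DESeq2 1 rose and 2 fell. Without knockout replicate 1, 1 rose. Cpt1a was not called with DESeq2 or without knockout 1, 0.49 to 0.58. Scd1 was not called with DESeq2 or the length and GC correction or without wild type 2 or 3 or knockout 1 or 2, -0.33 to -0.23.

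Among chromatin genes, 9 of 19 Polycomb genes fell and 2 rose, also when adjusted over the list alone (median -0.36, camera adjusted p = 0.0597). Ezh2, the H3K27 methyltransferase gene, fell from 349 ± 32.4 to 148 ± 5.75 CPM, Pcgf5 from 74.1 ± 2.88 to 32.6 ± 5.37 CPM and Phf19 from 13.9 ± 3.98 to 3.27 ± 2.35 CPM, with Rnf2 at a log2 fold change of -0.86 (not called with DESeq2 or without wild type 1 or knockout 2, -0.90 to -0.63). Jarid2 rose from 145 ± 2.16 to 214 ± 18.2 CPM. The median was -0.18 without wild type replicate 3 and -0.17 after the length and GC correction. The list was called without the filter (0.0221) and when wild type replicates 2 or 3 or knockout replicates 1 or 3 were left out (camera adjusted p = 0.0305 to 0.0498). With DESeq2 5 members fell, and 1 rose with DESeq2 or without any 1 library other than knockout replicate 2. The Hox list had 1 tested gene, Pbx2 (log2 fold change -0.45), which was not called with DESeq2 or without wild type 1 or 2 or knockout 2 or 3, -0.48 to -0.34. Of 14 AP-1 and partner transcription factors 6 rose and 3 fell, also when adjusted over the list alone (median 0.41, camera adjusted p = 0.0597). Jund rose from 839.6 ± 56.02 to 1777 ± 68.7 CPM, Jun from 105 ± 12.7 to 219 ± 8.62 CPM, Fosl2 from 75.5 ± 10.97 to 147 ± 10.3 CPM and Junb from 167 ± 15.9 to 316 ± 46.8 CPM. Mafk (-1.27), Nfatc1 (-0.81) and Bach1 (-0.66, not called with DESeq2, voom, non-robust estimation, edgeR, thinned reads or the length and GC correction or without wild type 1 or 2 or knockout 1 or 3, -0.72 to -0.39) fell. The AP-1 list was called with library totals alone (0.0435), without the filter (0.0472), with thinned reads (0.0488) and when wild type replicates 1 or 2 or knockout replicates 2 or 3 were left out (camera adjusted p = 0.0129 to 0.0410).

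Interferon-stimulated genes changed in both directions, with 9 of 24 lower and 5 higher, or 10 and 5 when adjusted over the list alone (camera adjusted p = 0.145). Ifi203 fell from 231 ± 19.6 to 64.3 ± 17.3 CPM, Gbp5 from 59.3 ± 7.71 to 22.4 ± 3.80 CPM and Stat2 by a log2 fold change of -0.95 (not called with DESeq2 or without wild type 2 or knockout 3, -0.92 to -0.66). Isg20 rose from 43.9 ± 11.1 to 102 ± 9.43 CPM and Bst2 from 23.4 ± 0.775 to 48.8 ± 2.66 CPM, and Ifi204 had 40 knockout and 3 wild type reads, a ratio of 11.2 (3.55 to 56.4). Gbp4 rose by 0.46. The RNA sensor gene Ifih1 rose by 0.80 (not called with library totals, no filter, a 5 CPM filter, DESeq2, non-robust estimation, edgeR or thinned reads or without wild type 1 or 3 or knockout 1 or 2, 0.55 to 0.81). Without knockout replicate 1, 2 rose and the list was called (camera adjusted p = 0.0234), and without knockout replicates 2 or 3, 5 fell. DESeq2 called 3 higher and 4 lower, library totals 3 and 12, and thinned reads 3 and 7. Of 21 p53 targets 4 rose and 4 fell, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.879 with an upward direction). Btg2 (log2 fold change 0.92) and Mdm2 (0.67) rose with Cdkn1a, and Fas fell from 12.8 ± 3.33 to 3.05 ± 2.32 CPM, with Gtse1 at -1.06, Tap1 at -0.59 and Trp53inp1 at -0.55. Of 18 BCL2 family and death receptor genes 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.770). Bcl2 itself fell from 1064 ± 42.6 to 684 ± 64.1 CPM and Birc2 by -0.81, while Bax rose by 0.77. The others were Bad (0.71, not called with DESeq2 or without wild type 3 or knockout 2, 0.51 to 0.71), Mcl1 (0.30, not called with library totals or DESeq2 or without wild type 2 or knockout 2 or 3, 0.18 to 0.30) and, lower, Xiap (-0.32, not called with no filter, a 5 CPM filter, DESeq2, voom, non-robust estimation, thinned reads or the length and GC correction or without wild type 2 or 3 or knockout 1, 2 or 3, -0.39 to -0.06), with Fas. Without wild type replicate 2 (which also lost Bax, at 0.49), without knockout replicate 2 or with DESeq2, 2 of them rose. Of 25 autophagy and lysosome genes 6 rose and 0 fell, also when adjusted over the list alone. The protease gene Ctsd rose from 367 ± 36.8 to 1017 ± 42.6 CPM and the autophagy receptor gene Sqstm1 from 156 ± 14.8 to 296 ± 18.3 CPM, with Ctsz at 0.89 (not called with DESeq2 or thinned reads or without wild type 2 or knockout 2 or 3, 0.69 to 1.00) and Gabarap at 0.67 (camera adjusted p = 0.209). With DESeq2 3 of them rose, and 3 list members fell with library totals alone and 2 without knockout replicate 1.

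**Figure D2:**
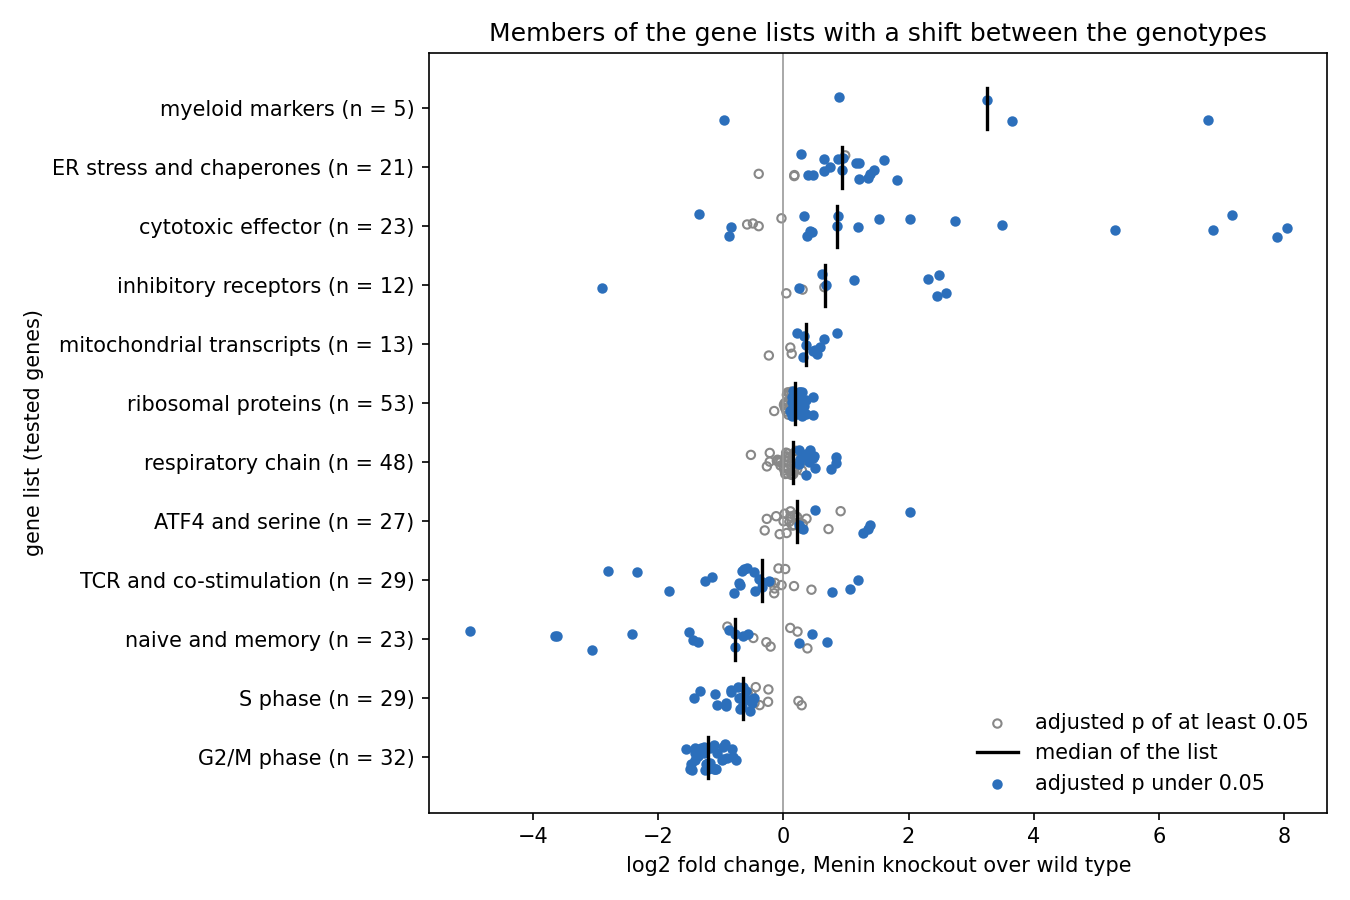
Log2 fold change, Menin knockout over wild type, of every tested gene in the 12 lists with a called shift (horizontal axis), with the number of tested genes per list in parentheses. Filled points have an adjusted p under 0.05, open points do not, and black bars are list medians, which run from -1.20 for G2/M phase to 3.25 for the 5 myeloid markers. Of these markers, Fcer1g, Itgam and Ly6g passed the filter only through their knockout reads. The bars for the respiratory chain (0.15) and ribosomal proteins (0.18) lie near 0, and with library totals alone 2 respiratory chain genes and 1 ribosomal protein gene fall.

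Markers of other cell types were mostly listed at 0 or too low to test, and those that could be tested moved apart. Of 22 myeloid markers 5 were tested, and 4 rose and 1 fell, also when adjusted over the list alone (median 3.25, camera adjusted p = 6.72e-04, adjusted p = 0.131 with an estimated correlation and 0.0511 by ranks). Next to Fcer1g they were Itgam, with 70 knockout and 2 wild type reads and a ratio of 29.3 (7.81 to 247), Ly6g (from 1.82 ± 1.58 to 23.2 ± 10.5 CPM) and Ly6c2, which wild type CD8 T cells also expressed (from 727 ± 53.4 to 1339.9 ± 78.98 CPM). Cd68 fell from 21.3 ± 3.77 to 11.3 ± 5.30 CPM, and was not called with DESeq2 or without wild type replicates 2 or 3 or knockout replicate 1. Fcer1g, Itgam and Ly6g had 2, 2 and 6 wild type reads and passed the filter only through their knockout reads. Myeloid markers low in both genotypes did not enter, so the filter favoured an upward shift of this list. Without the filter the median of the myeloid list lay lower. Of 4 tested dendritic cell markers Xcr1 rose from 1.53 ± 1.40 to 21.6 ± 5.80 CPM and Bst2 also rose, with 0 lower, also when adjusted over the list alone (camera adjusted p = 0.326), and 1 fell with library totals alone. Of 5 tested NK and innate lymphoid markers 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.376). The Fc receptor gene Fcgr3 was at 0 reads in every wild type library and at least 8.34-fold higher in the knockout (24.8 ± 0.930 CPM), and Klrb1c was higher too. Eomes was called higher in fewer settings, with a log2 fold change of 0.13 to 0.25 in the 9 where it was not called, among them library totals, DESeq2 and the omission of wild type replicates 1 or 3 or knockout replicates 2 or 3. Il7r fell from 114 ± 16.3 to 66.5 ± 10.4 CPM and Gata3 from 103 ± 17.6 to 59.1 ± 2.23 CPM. Several markers are shared with other lists, Fcer1g with NK receptors, Bst2 with interferon genes, and Eomes, Il7r and Gata3 with T cell programs. The median of the NK and innate lymphoid list, 0.25, was the same with Fcgr3 at its bound. Of 4 tested genes of CD4 and regulatory T cells Lrrc32 fell (log2 fold change -0.58) and 0 rose, also when adjusted over the list alone (median 0.10, mean -0.03, camera adjusted p = 0.929). The B cell list had 1 tested gene, H2-Ab1 (126 ± 7.74 CPM in wild type and 111 ± 9.34 CPM in knockout cells, adjusted p = 0.263), which was called lower with library totals alone and after the length and GC correction (-0.34 to -0.30). The stromal list had 2, of which Vim fell from 3815 ± 122 to 2963 ± 200.1 CPM (1 rose and 1 fell when adjusted over the list alone), and the gamma-delta T cell and erythroid lists had 0. T cell receptor and immunoglobulin gene segments are listed at 0 in every library, which is uninformative. The lack of tested genes therefore does not show that gamma-delta T cells or B cells were absent.

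Signs of RNA quality and of library composition moved with genotype. Ribosomal protein genes were slightly higher in the knockout, with 38 of 53 higher and 0 lower, or 42 and 0 when adjusted over the list alone (median 0.18, camera adjusted p = 1.07e-11, adjusted p = 0.221 with an estimated correlation). Rps28 rose from 1468 ± 80.1 to 2044 ± 72.4 CPM, with Rpl38 at 0.37 (not called after the length and GC correction) and Rpl35 at 0.36. With library totals alone 20 rose and 1 fell (median 0.06), and after the length and GC correction 19 rose and 1 fell (median 0.04). Of 13 transcripts of the mitochondrial genome 10 rose and 0 fell, or 11 and 0 when adjusted over the list alone (median 0.35, camera adjusted p = 9.15e-06, adjusted p = 0.352 with an estimated correlation). The level of mt-Co3 rose from 1861 ± 77.8 to 2927 ± 151 CPM and mt-Nd3 from 280.5 ± 46.2 to 503 ± 23.2 CPM, and mt-Nd4l and mt-Nd4 at 0.58 and 0.53. Under library totals 6 of them rose (median 0.23). Of 11 heat shock genes 5 rose and 3 fell, also when adjusted over the list alone. Among these were Hsph1 at a log2 fold change of 0.77, Hspa4l at -1.01 and Hspa8 at -0.21 (camera adjusted p = 0.535). Hsp90ab1 rose by 0.13. Bag3 (0.97) was not called with DESeq2 or without wild type 1 or knockout 1 or 3, 0.73 to 1.02. Hspd1 (0.22) was not called with library totals or DESeq2 or without wild type 2 or 3 or knockout 2, 0.10 to 0.23. Hsp90aa1 (0.17) was not called with library totals or without knockout 2, 0.05 to 0.16. Dnaja1 fell (-0.37) but not after the length and GC correction. Under library totals 2 list members rose, and 3 with DESeq2 or without knockout replicate 2.

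The share of reads in the 10 most abundant genes was 9.63 ± 0.0850% in knockout and 8.34 ± 0.112% in wild type libraries. The share in ribosomal protein genes was 13.1 ± 0.198% against 12.6 ± 0.114%. Total reads, genes detected and both of these shares were higher in 3 of 3 knockout libraries than in any wild type library (exact permutation p = 0.1 each, the smallest that 3 against 3 libraries can give; adjusted p = 0.125 over 5 measures). The share of mitochondrial transcripts was 2.39 ± 0.212% against 2.11 ± 0.0895% (exact permutation p = 0.2, adjusted p = 0.2). Knockout libraries held a mean of 395 more detected genes than wild type libraries, and 27 more among the genes that passed the filter.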

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

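Pseudocounts of 0.5 and 4, thinned reads and the length and GC correction were chosen after seeing the data. The edgeR quasi-likelihood test, planned as the main test, was added as an alternative only then. The number of changed genes lay between 2450 and 2900 under the settings other than DESeq2's Wald test and the omission of a library, against 2592. DESeq2's Wald test called 1703 genes (869 higher, 834 lower), and the cause was not tested. Without any 1 library the calls ranged from 2136 to 2342 (1078 to 1199 higher, 1054 to 1163 lower, 761 to 820 changed at least 2-fold), with 2 libraries left in 1 genotype. Without the filter 13418 genes were tested and 1235 changed at least 2-fold against 763, because more genes of low counts entered. With a pseudocount of 4, 594 did. After the length and GC correction 16 of the 2592 calls changed sign, and with library totals alone 5 did.

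The replicate block called 2672 genes, of which 2583 were shared. Samples share only a number. Same-numbered libraries deviated together by correlations of 0.04, 0.04 and 0.02 across genes. Each library correlated best with its own number, a hint from the data and not from the design. These correlations are weak, and with 3 libraries per genotype such a match can arise by chance, so it does not show a pairing. Under the block the Polycomb list (0.0491) and the AP-1 list (0.0250) were called, and no other list and no named gene changed its call. Counts that moved by over 1.5 times were those of secreted factors of senescent cells that rose (2), hypoxia genes that rose (2) and autophagy genes that fell (1), and some others moved by less.

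Of the named genes' values under alternatives, 3530 kept direction and side of the threshold, 204 lost the call and 3 gained one. For lists 670 did, 35 gained a call and 15 lost it. Of 36 tested lists 12 were called by camera, 3 with an estimated correlation (cytotoxic effectors, G2/M and unfolded protein response) and 26 by fry, which does not compare a list with other genes. No called list or called named gene changed direction. Low genes that enter without the filter moved the medians of the cytotoxic (0.45), inhibitory receptor (0.31), Polycomb (-0.16) and myeloid (0.81) lists toward 0. Under library totals all list medians lay lower, some of uncalled lists (among them cholesterol and autophagy) fell below 0, and calls turned from 1330 higher and 1262 lower to 917 and 1745. Knockout libraries had 395 more detected genes than wild type, and 27 more among filtered genes only. At this depth 33 of 50 simulated 1.5-fold changes were called, so changes of this size or smaller can be missed. Low genes were not seeded in the simulation, so the rate does not cover them.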

Other observations

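The tests of myeloid and NK markers, CD3 and CD8 genes, scaling, transcript length, splits of the libraries, neighbouring genes at matched expression and groups of genes by symbol stem were chosen only after the result was seen.

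Further groups appear when genes are gathered by the stem of their symbol. Of 245 stems with at least 5 tested genes, 14 shifted by camera (adjusted over the stems), though each has an adjusted p = 0.773 with an estimated correlation. Of 5 genes with the stem Lgals, 2 galectin genes and 1 gene of a galectin-binding protein rose and 0 fell: Lgals3 from 606 to 1544 CPM, Lgals1 from 998 to 1773 and Lgals3bp from 49.6 to 155 (median 0.83, adjusted p = 0.0337). Of 12 dual-specificity phosphatase genes, some of which restrain MAP kinases, 6 rose and 0 fell (5 and 0 with library totals alone; median 0.71, adjusted p = 0.0281), with Dusp5 from 99.9 to 255 and Dusp6 from 181 to 375 CPM. Of 9 myosin genes 5 rose, led by Myo1e (2.73 to 61.1 CPM) and Myo10 (33.7 to 195 CPM), and Myo9a fell (adjusted p = 0.0187). Of 7 annexin genes 4 rose and 0 fell, Anxa5 from 60.97 to 171 CPM, Anxa1, Anxa2 and Anxa7 (adjusted p = 0.0420, and 0.0750 with library totals alone, which lose Anxa7). Of 8 Gimap genes, GTPases of lymphocyte survival, Gimap1, Gimap4, Gimap6 and Gimap7 fell and 0 rose (median -0.45, adjusted p = 0.0210). Of 22 genes with the stem Kif, kinesin genes apart from Kif1bp, 12 fell, with Kif11 from 185 to 68.98 CPM, and Kif5b rose except with library totals alone (adjusted p = 4.57e-04). All 6 Smc and all 7 Cdca genes fell, as did 7 of 9 genes with the stem Mcm, and several of these belong to the cell cycle lists.

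Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many genes as 2592, and the highest other split called 0. Every other split puts both genotypes in each group, so the genotype difference adds to the spread within groups. A count of 0 there was largely fixed in advance and does not measure false calls. With 10 splits the share cannot go below 0.1.

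Genes known from innate cells (Fcer1g, Itgam, Ly6g, Fcgr3, Klrb1c, Xcr1 and Mcpt8) were higher in knockout cultures, which could reflect other cells in them, although the cells were sorted as naive CD8 T cells before culture. Summed markers argue against neutrophils, monocytes or macrophages, and NK cells as the main source of the Fcer1g level. The higher of the summed neutrophil and monocyte sets reached 5.54% of that level and the NK set 3.02%. Tyrobp, abundant in those cells, had 17 knockout reads against 615 of Fcer1g, S100a8 had 2 and Ncr1 had 1. Some markers still rose at few reads: Tyrobp had 3 in wild type, and Cd14 had 16 knockout and 0 wild type reads. Csf1r went the other way, with 0 and 10. A small share of such cells therefore stays open. Dendritic cells, marked by Xcr1, stay open as well. Itgax had 13 knockout and 0 wild type reads, but their marker set summed to 22.1 CPM in knockout and 22.2 CPM in wild type libraries. Replacement of CD8 T cells by cells without CD3 would lower T cell genes alike, and the median log2 fold changes of Cd3d, Cd3e and Cd3g and of Cd8a and Cd8b1 lay 1.29 apart, but Cd247 (-0.47) and Cd2 (-0.72) fell with the latter and a small share of such cells would hardly lower CD3 genes, so this stays open, as does replacement by T cells without Cd4, itself at 0 reads. Basophils or mast cells stay open too. Their markers summed to 17.1% of the Mcpt8 level (SD 5.73 over 3 libraries), below the bound set beforehand by less than that SD. Nearly all of the sum came from Cpa3 (83 knockout and 4 wild type reads), which goes with these cells. Against them, Fcer1a, Ms4a2, Prss34, Gata2 and Cd200r3 had 0 knockout reads and Hdc had 1, beside 482 of Mcpt8. Expression by the knockout T cells themselves stays a hypothesis.

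The small rise of ribosomal protein and respiratory chain genes may follow transcript length and GC content. With the trend fitted on genes outside the ribosomal, respiratory chain and mitochondrial lists and then removed, the ribosomal median went from 0.18 (bootstrap over genes 0.15 to 0.23) to 0.03 (0.00 to 0.09), which keeps 14.9%. The respiratory chain median went from 0.15 (0.07 to 0.23) to 0.02 (-0.02 to 0.06), which keeps 10.1% and leaves an interval that spans 0. The mitochondrial transcripts kept 128% of their median, so the trend of the other genes did not account for their rise. That trend may not hold for mitochondrial transcripts (median length 784 nt against 3154 nt of all tested genes), so a technical source stays open. The ribosomal (954 nt) and respiratory chain (870 nt) lists were as short and also outside the fit. The same limit therefore applies to the shares that they kept. Scaling stays open for the ribosomal shift, since library totals alone kept 33.9% of its median. What made the trend (RNA quality, library preparation or genotype) was not tested.

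Changed genes may come in chromosomal neighbourhoods: of 5196 pairs of neighbouring tested genes within 100 kb, 412 were called in the same direction, against a mean of 281 in 10000 shuffles of the calls (one-sided permutation p = 0.0001, the smallest these shuffles can give). Without pairs that share a symbol stem the count was 369 against 272, and with overlapping or closer pairs than 1 kb also left out and shuffling within 10 classes of mean expression it was 298 against 215 (permutation p = 0.0001 for both). The stem ends before the first digit, so similar genes named by letters, such as Gzmd and Gzme, stayed in both counts. The shuffles were not matched for transcript length or GC content. The longest nuclear run held 9 genes on chromosome 14 (Sdr39u1, Mcpt8, Ctsg, Gzme, Gzmd, Gzmg, Gzmf, Gzmc and Gzmb) over 365 kb, all higher. Others held 7 on chromosome 5 (Speer1, 5 predicted genes and Sema3d) over 1641 kb, all higher, 6 on chromosome 3 with Gbp2, Gbp3, Gbp5 and Gbp7 over 3712 kb and 6 on chromosome 7 with 5 Trim genes over 1137 kb, all lower. Runs were taken over consecutive tested genes at any distance and were not compared with shuffles. A long span therefore shows only that no other tested gene lay between. Whether reads shared by similar genes made some of the runs was not tested. Variants carried along with the targeted allele could add calls near Men1, but 41 of 129 genes within 5 Mb were called (31.8%, exact 95% interval 23.9 to 40.6%) against 32.9% elsewhere (two-sided Fisher's exact p = 0.850), and the bound set beforehand was ill-chosen, since that interval leaves a modest excess open.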
